A study of Mus musculus with 2 samples.

How the data were processed

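Promoter Capture Hi-C was carried out by the submitters on F121-6 hybrid mouse ES cells in 2 samples, labelled replicates 1 and 2. Per the labels' protocols, cells were fixed in 2% formaldehyde, chromatin was cut with HindIII and ligated inside the nucleus, baits targeted 22225 promoters, and libraries were sequenced with paired reads of 100 bp. The submitters' processing notes name Bowtie2 and the mm10 assembly. How reads were assigned to alleles, which filters and duplicate removal were used, and how both samples were merged is not given in the sources used here.

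The deposited table gives whole-number interaction counts for the 129 and the Cas allele in windows of 50 kb, not normalised, and a distance for each allele, taken to be in bp. The distances are multiples of 500 bp, 80.0% of them of 1000 bp, and whether they are means or medians is not given in the sources used here. Both samples carry the same column labels, so each column was taken as the pooled value of the group, and alleles were compared within 1 pooled dataset. Nothing in the labels says that the replicates came from separate cultures. Since no column belongs to a single sample, no replicate could be left out. Window starts, which count from 0 in the table, were raised by 1 to give coordinates as a genome browser shows them.

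Processing can shape the values in 3 ways. Reads of the Cas allele carry more differences from a reference close to 129 and may be lost in mapping, which would raise the 129 share. Fragments are captured by baits, so the count of a window follows the number of baited fragments in it. An interaction may be counted at both of its ends, so counts are not independent molecules, and all intervals, floors and tests cover counting error only unless the beta-binomial test is named.

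The share of 129 was computed on summed counts with exact Clopper-Pearson 95% intervals and a jackknife over the 19 chromosomes. Window ratios were log2((129 + 1)/(Cas + 1)) minus the autosomal median. Windows with a summed count of 10 or more were tested by a two-sided exact binomial test against the autosomal 129 share, with Benjamini-Hochberg adjustment at 0.05. The alternative was a beta-binomial test with a single overdispersion for each kind of unit, estimated over all units of that kind. It was 0.0165 for windows of 50 kb, equal to a standard deviation of 6.35 percentage points of the 129 share between windows, 0.0109 for gene loci and 0.0052 for regions of 1 Mb, so a window and the locus it holds can have different adjusted p. Distances were compared as log2 ratios in windows with 10 or more interactions on each allele, without a test. Regions of 1 Mb needed a summed count of 50 and 3 windows. Bootstraps over chromosomes used 500 draws and neighbouring windows were compared with 100 shuffles. Where an allele had no count, folds are lower bounds against 3 counts.

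The design was fixed before the data were examined: the tests, the 16 gene lists, the rule for named items and the alternatives, apart from those said to be added later. The rule named the 12 windows per direction with the largest ratio among those called with a summed count of 30 or more, the 8 per direction with the largest distance ratio at 20 or more per allele, the 3 regions of 1 Mb per direction with the smallest p, and up to 2 list members per direction at a summed count of 20 or more. Genes known only by model or clone numbers were counted and not named, and a few items that the rule or the later choice picked are not reported here. Genes were placed by their RefSeq positions on the same assembly, GRCm38, which put 42060 genes, 18577 of them protein-coding, in 1 or more windows. Strand was not used, so a gene stands for every window its body overlaps, not its promoter alone. For each list, the percentile of its median was found among 10000 random lists of equal size drawn from protein-coding loci matched on deciles of the summed count. The list of X inactivation and escape genes and the comparison of X with autosomes were not analysed here, because the analysed table covers chromosomes 1 to 19.

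The tests were tested on simulated data over the same 43762 windows, with 50 windows changed at each of 4 folds. With binomial counts, the binomial test recovered 48% of windows changed 1.25-fold, 86% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 4 unchanged windows. With counts simulated at the observed overdispersion, the binomial test called 59.1% of unchanged windows, while the beta-binomial test called 1 window. The beta-binomial test recovered 0% of windows changed 1.25-fold or 1.5-fold, 6% at 2-fold and 78% at 4-fold. These counts were simulated with the same single overdispersion as the test, so the 1 false call does not cover windows with a wider spread. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The alternatives were other count minimums, thresholds, null shares, pseudocounts and centres, the beta-binomial spread, other region sizes, a cap on single windows, pairs without adjacent windows, and other matching of the random lists.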

Results

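The chromosome contacts of promoters were measured separately on the 2 parental alleles of a hybrid mouse embryonic stem (ES) cell line, F121-6, whose cells carry 1 set of chromosomes from the 129 strain and 1 from Mus castaneus (Cas). Promoter Capture Hi-C cuts and religates crosslinked chromatin inside the nucleus and then enriches, with RNA baits, the ligation products that hold a promoter. The cells were female and were grown on inactivated mouse embryonic fibroblasts as feeders. Both samples, replicates 1 and 2, belonged to the same group, and the table analysed here holds 1 pooled value per allele, so no spread between replicates could be given. Every test below therefore covers counting error or the spread between windows in these pooled libraries.

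The table holds an interaction count and an interaction distance on each allele for 43941 windows of 50 kb on chromosomes 1 to 19 of mm10, 2197 Mb in all. Interaction counts summed to 50842396 on the 129 allele and 37470557 on the Cas allele. The median window had 565 interactions on 129 (quartiles 287 and 1553) and 405 on Cas (quartiles 200 and 1136). The count was 0 on both alleles in 109 windows and on a single allele in a further 96. Windows with genes had more contacts and shorter ones. Because the baits target promoters, the capture itself can set these differences in count and distance. The 18534 windows without a protein-coding gene had median counts of 324 on 129 and 227 on Cas, with median distances of 912 and 906 kb. The 18150 windows with 1 such gene had median counts of 716.5 and 523 and distances of 263 and 266.5 kb. In the 7257 windows with 2 or more, the counts were 2369 and 1775 and the distances 97 and 101 kb.

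The first comparison asked whether both alleles were recovered alike. The 129 allele held 57.57% of all interactions (exact Clopper-Pearson 95% interval 57.56 to 57.58%), and its share was above that of Cas on each of the 19 chromosomes. Chromosome 10 stood apart, with 61.1% of its interactions on 129, while the other 18 chromosomes lay between 55.3% on chromosome 14 and 58.5% on chromosome 13. Chromosome 8 was close to chromosome 14, at 55.9%. The share on 129 was 58.3% in windows without a protein-coding gene, 57.6% in windows with 1 and 57.2% in windows with 2 or more. Leaving out each chromosome in turn gave shares of 57.4 to 57.7%, with a jackknife standard error of 0.243 percentage points over chromosomes, so the share was known less well than its counting interval states.

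The median window had a log2 ratio of 129 to Cas of 0.45, and every ratio below was taken relative to this value unless raw counts are given. On that centred scale the median window of chromosome 10 lay at 0.24 (95% bootstrap interval over its windows 0.22 to 0.25). That interval takes windows as independent, and since neighbouring windows were correlated it is likely too narrow. The medians of the other 18 chromosomes ran from -0.12 on chromosome 14 to 0.07 on chromosome 17. All 13 bins of 10 Mb on chromosome 10 were above 0, between 0.10 and 0.36. On chromosome 8 this held for 1 of 13 bins and on chromosome 14 for 2 of 12.

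**Figure D1:**
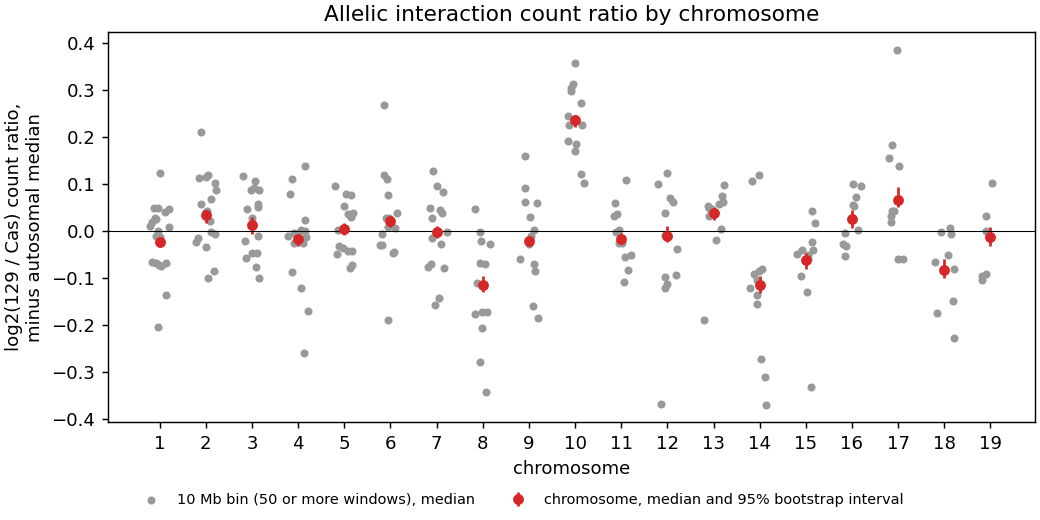
Log2 ratio of 129 to Cas interaction counts (y axis, minus the autosomal median) for each autosome (x axis), with grey points for the medians of 10 Mb bins and red points for the chromosome median. Bars are 95% bootstrap intervals over single windows, which do not allow for the correlation of neighbours. All 13 bins of chromosome 10 lie above 0, and its median of 0.24 is above that of the other 18 chromosomes.

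The next comparison asked which windows had unequal contacts on the alleles. The largest imbalance at a high count was in the window that holds the start of the annotated span of Slc39a12, a zinc transporter gene, on chromosome 2 (14350001 to 14400000). It had 2732 interactions on 129 and 44 on Cas, a 129 share of 98.4% (95% interval 97.9 to 98.8%) and a centred log2 ratio of 5.47. A window with the olfactory receptor genes Olfr746 and Olfr747 on chromosome 14 (50650001 to 50700000) had 677 interactions on 129 and 18 on Cas. A window without a protein-coding gene on chromosome 6 (43900001 to 43950000) had 2451 and 147. In the opposite direction, a window of Sema5a, which encodes a semaphorin of axon guidance, on chromosome 15 (32250001 to 32300000) had 479 interactions on 129 and 2566 on Cas, a 129 share of 15.7% (14.5 to 17.1%).

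Of the 12 windows with the largest ratios towards 129, 6 had no interaction on Cas. These were a window on chromosome 19 (33650001 to 33700000) with 101 interactions on 129, at least 33.7-fold higher, and the window of Slc22a30, a gene of the organic ion transporter family, on chromosome 19 (8300001 to 8350000) with 56, at least 18.7-fold higher. The window of the cytochrome P450 gene Cyp3a44 on chromosome 5 (145800001 to 145850000) had 51, at least 17.0-fold higher. A window on chromosome 7 (47850001 to 47900000) and another on chromosome 13 (3100001 to 3150000) each had 42, and a window on chromosome 6 (70350001 to 70400000) had 36 with none on Cas, at least 12-fold higher. These bounds set the allele at 0 to 3 interactions in the pooled counts. The lower limits of the exact two-sided 95% intervals of the ratio were smaller, at 26.9 for the window with 101 interactions, 14.7 for Slc22a30, 13.3 for Cyp3a44, 10.9 for the windows with 42 and 9.27 for the window with 36. Adjoining windows on chromosome 2 had 150 interactions against 7 (11800001 to 11850000) and 157 against 1 (11850001 to 11900000). A window on chromosome 12 (92850001 to 92900000) had 67 against 3. The ratio was 157 (95% interval 27.8 to 6240) where Cas had 1 interaction and 22.3 (7.32 to 111) where it had 3. Near the Cyp3a44 window, that of Cyp3a41a (145700001 to 145750000) went the opposite way, with 0 interactions on 129 and 15 on Cas. The windows adjoining that of Cyp3a44 were at 0.32 and 0.34. On chromosome 6, the nearby window from 70250001 also went the opposite way, with 9 on 129 and 44 on Cas. The cause of these opposite calls was not tested.

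The windows with the largest ratios towards Cas had no named protein-coding gene in 9 of 12 cases. A window on chromosome 18 (72900001 to 72950000) had 232 interactions on 129 and 2282 on Cas, 1 on chromosome 15 (17550001 to 17600000) had 166 and 1296, 1 on chromosome 1 (172900001 to 172950000) had 361 and 2322, and 1 on chromosome 14 (104600001 to 104650000) had 577 and 2570. Apart from the Sema5a window given above, the remaining windows had low counts. They included the vomeronasal receptor genes Vmn1r59 and Vmn2r28 on chromosome 7 (5450001 to 5500000), with 9 interactions on 129 and 55 on Cas, and Vmn1r173 on chromosome 7 (23700001 to 23750000), with 7 and 36. Windows without a named protein-coding gene lay on chromosomes 14 (52700001 to 52750000), 2 (175150001 to 175200000) and 8 (55400001 to 55450000). They had 1 and 36, 2 and 28, and 6 and 42 interactions on 129 and Cas. Where 129 had 1 and 2 interactions, its share was 2.70% (0.0684 to 14.2%) and 6.67% (0.818 to 22.1%). Those on chromosomes 1 (109750001 to 109800000) and 6 (70250001 to 70300000) had 39 and 186, and 9 and 44.

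Further windows with 1000 or more interactions, chosen after their values were seen, named more genes. Towards 129 they included Macrod2 on chromosome 2 (141600001 to 141650000; 3205 on 129 and 199 on Cas) and the unconventional myosin gene Myo16 on chromosome 8 (10250001 to 10300000; 2480 and 157). Erich3 on chromosome 3 (154700001 to 154750000) had 3385 and 242, and Lrp11 on chromosome 10 (7550001 to 7600000) had 1701 and 139. Towards Cas they included Btla, a gene of an inhibitory lymphocyte receptor, on chromosome 16 (45200001 to 45250000), with 1168 on 129 and 3568 on Cas. Slco3a1 on chromosome 7 (74550001 to 74600000) had 553 and 1653, Zfp365 on chromosome 10 (67900001 to 67950000) had 821 and 2367, and Nlrp1b, an inflammasome sensor gene, on chromosome 11 (71200001 to 71250000) had 691 and 1796. The windows on either side of Nlrp1b were shifted the same way, with centred log2 ratios of -1.07 and -1.38.

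The two-sided exact binomial test against the autosomal 129 share, with Benjamini-Hochberg adjustment at 0.05, called 22494 of 43762 windows with 10 or more interactions. Of these, 11849 were higher on 129 and 10645 on Cas. Against an equal share of both alleles the same test called 36272 windows, 96.5% of them higher on 129, whereas 52.7% of the calls were higher on 129 with the autosomal share. The centred log2 ratios had a standard deviation of 0.45 and quartiles of -0.19 and 0.22, and 1455 windows differed by 2-fold or more. Counting error alone gave a median standard deviation of 0.04 in windows above the upper count quartile, where the observed value was 0.36. A beta-binomial test, which takes a single value for this spread over all windows, called 413 windows, 318 higher on 129 and 95 on Cas. The spread was wider in windows with 10 to 495 interactions, with a standard deviation of 0.64 against 0.17 from counting error. The test does not allow for that, so calls at low counts are less certain. All 24 windows named first passed the beta-binomial test. Of these, 2 of the 12 towards 129 and 5 of the 12 towards Cas had 1000 or more interactions. Of the 413 windows, 227 had 1000 or more interactions, 189 higher on 129 and 38 on Cas. A protein-coding gene lay in 53.8% of the windows called higher on 129 and in 46.3% of those higher on Cas by that test, against 57.8% of all windows tested.

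**Figure D2:**
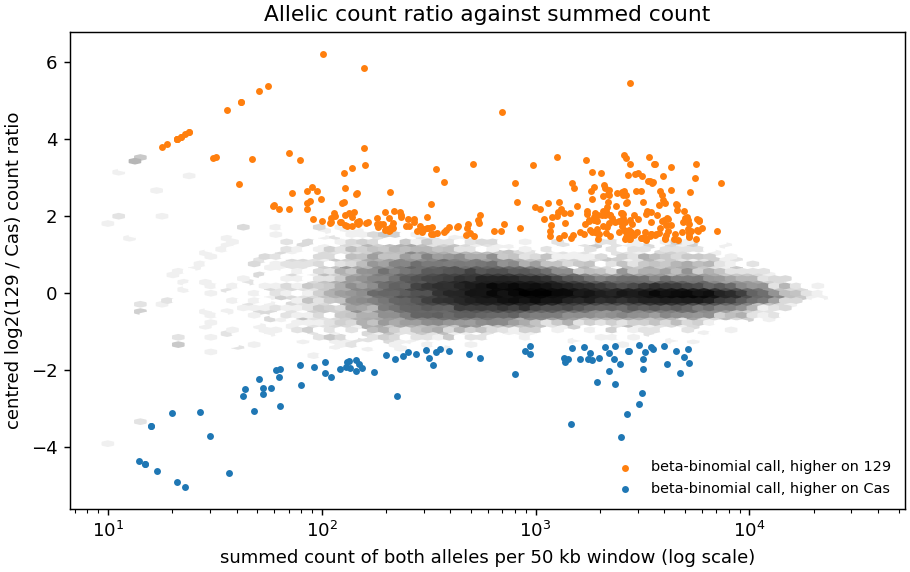
Centred log2 ratio of 129 to Cas counts (y axis) against the summed count of both alleles on a log axis (x axis) for the 43762 windows tested, with grey shading for their density. Coloured points are the 413 windows called by the beta-binomial test, 318 higher on 129 in orange and 95 higher on Cas in blue.

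The Slc39a12 window was a narrow feature of its region. Slc39a12 spans 14388316 to 14494977 on chromosome 2 in the annotation of the same assembly, so the window covers its first positions and sequence before it. The adjoining windows had centred log2 ratios of 0.20 and 0.51. Over the other windows within 1 Mb, which cover Vim, St8sia6, Stam, Mrc1 and Cacnb2 among others, the median was 0.38 with a range of -0.47 to 1.36. On Cas, the 44 interactions of the window were fewer than the median of 137.5 in the 8 gene-free windows of this region. The 2732 interactions on 129 compared with a median of 280 in the same gene-free windows. The interval of the window's share allows for counting error only.

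**Figure D3:**
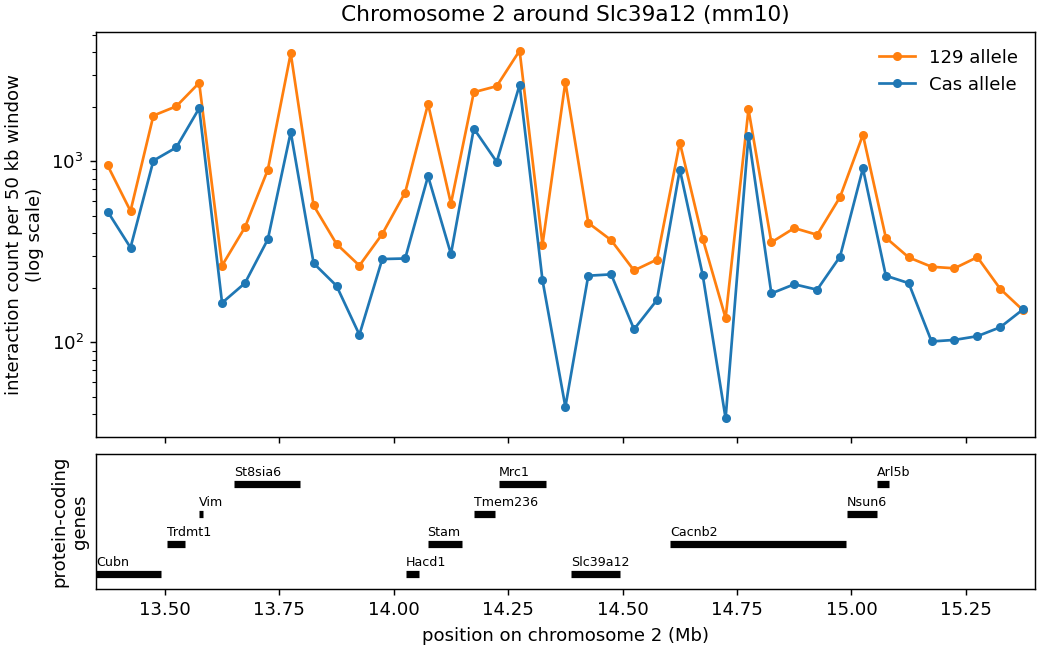
Interaction counts per 50 kb window on a log axis (y axis) along chromosome 2 around Slc39a12 (x axis, Mb), for the 129 allele in orange and the Cas allele in blue, with protein-coding genes drawn to scale beneath. The alleles are furthest apart in the window at the left end of Slc39a12, where 129 has 2732 interactions and Cas 44.

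The third comparison asked whether contacts reached further on either allele. At the middle of the distribution they did not differ: over 43555 windows with 10 or more interactions on each allele, the median log2 ratio of 129 to Cas distance was 0 (95% bootstrap interval over chromosomes -0.0047 to 0). The distance was longer on 129 in 21230 windows, longer on Cas in 21536 and equal in 789. Single windows differed widely, with a standard deviation of 0.89. The distance was at least 2-fold longer on 129 in 3646 windows and on Cas in 3804.

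At Kcnj3, which encodes an inwardly rectifying potassium channel, a window on chromosome 2 (55400001 to 55450000) had a distance of 14 kb on 129 and 2125.5 kb on Cas, with 3943 interactions on 129 and 578 on Cas. The next window in the same gene (55450001 to 55500000) had 65 and 11294 kb, and the window before it (55350001 to 55400000) had 76 and 8257 kb. A window of Macrod2 on chromosome 2 (141650001 to 141700000) had 46 kb on 129 and 5831 kb on Cas. Windows without a named protein-coding gene lay on chromosome 17 (94300001 to 94350000) and chromosome 10 (46300001 to 46350000 and 46500001 to 46550000). Their distances were 11, 52 and 161 kb on 129 and 3220.5, 16550 and 25284 kb on Cas. A window on chromosome 12 (115900001 to 115950000) had 136 and 15378 kb. In the opposite direction, a window of the netrin receptor gene Unc5d on chromosome 8 (29200001 to 29250000) had a distance of 1879 kb on 129 and 28 kb on Cas, with 599 and 1000 interactions. A window on chromosome 15 (38850001 to 38900000) had 10380 and 36 kb, and a window on chromosome 18 (72850001 to 72900000) had 2295 and 27 kb. The other 5 windows of largest ratio towards 129 had no named protein-coding gene and lay on chromosomes 4, 12 and 15. Of the 16 windows, 2 had a summed count of 1000 or more, the window of Kcnj3 with 4521 interactions and that of Unc5d with 1599. Some adjoined a window with a large count ratio and were shorter on the allele with more interactions there. The other 2 windows at Kcnj3 adjoined that with 3943 and 578 interactions, and the Macrod2 window adjoined one with 3205 and 199. The window on chromosome 18 adjoined one with 232 on 129 and 2282 on Cas, and 2 on chromosome 15 lay beside one with 166 and 1296. An interaction may be counted in both neighbours, so these need not be separate cases. No test was possible with 1 distance per allele and window, and how the distances of a window's interactions were summarised is not given in the sources used here.

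Count and distance were then set against each other. In the 283 windows called higher on 129 by the beta-binomial test that had 10 or more interactions on each allele, median distances were 156 kb on 129 and 479 kb on Cas. The distance was longer on Cas in 214 of them and on 129 in 67. In the 78 windows called higher on Cas, median distances were 535 kb on 129 and 355.5 kb on Cas, with 57 longer on 129 and 20 on Cas. The allele with more contacts thus had the shorter ones in most of these windows, as at Mcm4, where the distance was 17 kb on 129 and 1494.5 kb on Cas. Over all 43555 windows the relation was weak, with a Pearson r of -0.100 (95% bootstrap interval over chromosomes -0.120 to -0.082) and a Spearman rho of -0.062 (-0.076 to -0.050). In the 21556 windows with a summed count of 1000 or more, r was -0.271 (-0.303 to -0.240) and rho -0.127 (-0.143 to -0.111). In the other 21999, r was -0.029 (-0.053 to -0.0014) and rho -0.016, with an interval of -0.038 to 0.0032 that includes 0. These correlations run across windows, which are not independent replicates.

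The next comparison asked whether allelic differences were shared along the chromosome. Windows 50 to 200 kb apart had correlated count ratios, with r = 0.211 (95% bootstrap interval over chromosomes 0.173 to 0.251). The correlation fell to 0.136 at 200 kb to 1 Mb, 0.063 at 1 to 5 Mb and 0.034 at 5 to 20 Mb. The highest values in 100 shuffles of windows within chromosomes were 0.041, 0.035, 0.035 and 0.036, so the value at 5 to 20 Mb was within them. When each chromosome was centred on its own median, a setting added after the data were seen, the correlations were 0.184, 0.106, 0.031 and 0.0015. Correlations of distance ratios were lower than those of the uncentred count ratios, at 0.138 (0.122 to 0.156), 0.046, 0.00547 and 0.00049. Their highest shuffled values were 0.0081, 0.0050, 0.00541 and 0.0044. The distance value at 1 to 5 Mb was thus barely above the shuffles and that at 5 to 20 Mb within them. An interaction between neighbouring windows can enter the counts of both, and pairs of windows share members, so the correlations describe these libraries and carry no p-value.

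**Figure D4:**
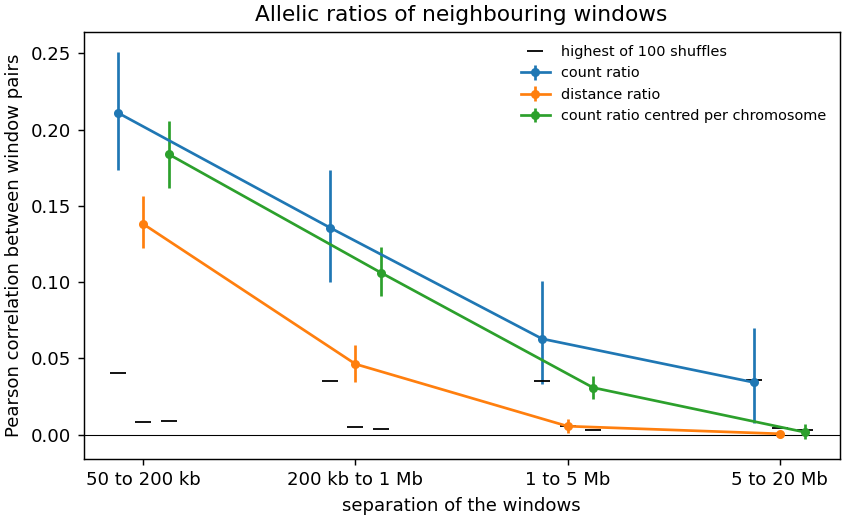
Pearson correlation of allelic ratios between pairs of windows (y axis) by their separation (x axis), for the count ratio, the distance ratio and the count ratio centred per chromosome. Bars are 95% bootstrap intervals over chromosomes and dashes the highest of 100 shuffles; the count ratio falls from 0.211 to 0.034.

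In windows of 1 Mb, the regions with the smallest p towards 129 included a cluster of olfactory receptor and Trim genes on chromosome 7 (104000001 to 105000000), where 64.0% of interactions were on 129 (95% interval 63.7 to 64.3%) and 17 of 19 windows of 50 kb lay above 0. A region on chromosome 10 (46000001 to 47000000) without a named protein-coding gene had 76.3% on 129, with 18 of 20 windows above 0. Another on chromosome 10 (121000001 to 122000000), with Wif1, a secreted Wnt inhibitor gene, and the kinase gene Tbk1, had 67.3%, with 19 of 20 above 0. Chromosome 10 as a whole was shifted, with its median window at 0.24. The median windows of its regions from 46000001 and 121000001 were at 0.73 and 0.45. Towards Cas, a region on chromosome 1 (174000001 to 175000000) with olfactory receptor genes and Fmn2 had 49.1% on 129, with 0 of 18 windows above 0. Another on chromosome 1 (172000001 to 173000000), with Vangl2, Nhlh1 and Ncstn, had 49.0% and 0 of 13. The region of Arhgef10, Myom2 and part of Csmd1 on chromosome 8 (15000001 to 16000000) had 46.0% and 4 of 20.

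The two-sided exact binomial test with Benjamini-Hochberg adjustment called 1941 of 2368 regions, 1109 higher on 129 and 832 on Cas. Against an equal share of both alleles it called 2322, of which 2272 were higher on 129 and 50 on Cas. Of the 6 regions named first, the region on chromosome 10 from 46000001 was the only region that passed the beta-binomial test, and the other 5 had Benjamini-Hochberg adjusted p of 0.125 to 0.911. That test called 10 regions, of which 6 were higher on 129. These lay on chromosome 17 (94000001 to 95000000, 85.3% on 129, with Mettl4), chromosome 10 (46000001 to 47000000), chromosome 3 (154000001 to 155000000, 71.3%, with Lhx8 and Erich3), chromosome 11 (27000001 to 28000000, 70.9%) and chromosome 8 (17000001 to 18000000, 70.8%, with Csmd1, and 50000001 to 51000000, 70.7%). The 4 higher on Cas were on chromosome 15 (17000001 to 18000000, 36.0% on 129), chromosome 7 (17000001 to 18000000, 43.5%, with Psg and Ceacam genes), chromosome 14 (72000001 to 73000000, 43.6%, with Fndc3a) and chromosome 18 (72000001 to 73000000, 43.6%, with Dcc, a netrin receptor gene). A single window of 50 kb held 49.6% of the interactions of the region on chromosome 17 and 39.9% of those of the region on chromosome 10.

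Gene lists were compared last, each as the counts summed over the windows that a gene's body overlaps, with genes in identical windows taken as 1 locus. "Higher" on an allele is relative to the genome-wide 129 share of 57.57%, so a locus called higher on Cas may still have more raw interactions on 129. The pluripotency genes showed no common direction: of 30 loci, 11 were higher on 129, 11 on Cas and 8 did not pass. Prdm14, a regulator of naive pluripotency, had 596 interactions on 129 and 246 on Cas (centred log2 ratio 0.82), and Mybl2 had 2817 and 1303 (0.66). Zfp42, known as Rex1, had 2071 and 2012 (-0.41), and the reprogramming factor gene Klf4 had 2751 and 2590 (-0.37). Lineage regulators that are silent in ES cells were as mixed, with 16 of 49 loci higher on 129, 20 on Cas and 13 not passing. The mesoderm gene T (1537 and 781; 0.52) and the shared window of Dlx1 and Dlx2 (3537 and 1899; 0.44) were higher on 129, and Pax3 (616 and 665; -0.56) and Irx3 (2091 and 2230; -0.55) on Cas. None of these loci passed the beta-binomial test. The medians of both lists, -0.016 and -0.0044, lay at percentiles 65.7 and 76.6 of 10000 random lists of equal size and count. The mean of the pluripotency list, 0.03, had the opposite sign to its median.

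Of 17 Hox loci, which form 4 clusters, 12 were higher on Cas by the binomial test, 4 on 129 and 1 did not pass, and none passed the beta-binomial test. In the HoxA cluster, Hoxa3 had 13855 interactions on 129 and 12333 on Cas (-0.29). The window of Hoxc8 to Hoxc11 (4275 and 2354; 0.41) and Hoxb13 (2542 and 1526; 0.28) were higher on 129. The list's median of -0.14 lay at percentile 2.98 for count, inside the central 95%, and its median log2 distance ratio of 0.12 at percentile 97.7. With neighbouring members averaged these percentiles were 34.2 and 85.5, and with each chromosome's own median as centre the count percentile was 0.74. Clustered protocadherins had 2 of 17 loci higher on 129, 7 on Cas and 8 not passing, with a median of -0.053 (percentile 38.9) that turned to 0.03 when centred on chromosome 18, where they all lie. Pcdhb8 had 1305 interactions on 129 and 1317 on Cas (-0.47), the window of Pcdhgc3 to Pcdhgc5 had 588 and 488 (-0.18) and did not pass, Pcdhb1 with Pcdhb2 had 7173 and 4830 (0.12), and the locus of Pcdhga6 to Pcdhga10 had 2894 and 1910 (0.15). None of them passed the beta-binomial test.

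Imprinted genes expressed from the paternal allele had 15 of 30 loci higher on 129, 7 on Cas and 8 not passing, with a median of 0.07 at percentile 98.2. Plagl1 (1819 interactions on 129 and 970 on Cas; 0.45) and Peg10 (1511 and 838; 0.40) were higher on 129, and Inpp5f (1843 and 2132; -0.66) and Mcts2 (6031 and 6627; -0.59) on Cas. Plagl1 lies on chromosome 10, whose median window was itself at 0.24. Those expressed from the maternal allele had 7 of 28 loci higher on 129, 8 on Cas and 13 not passing, with a median of -0.033 at percentile 53.2. The ubiquitin ligase gene Ube3a (5070 and 2897; 0.35) and Mirg (12719 and 8091; 0.20) were higher on 129, and H13 (8375 and 8800; -0.52), which holds Mcts2 within its span, and Gatm (3267 and 3196; -0.42) on Cas. Whether 129 or Cas was the mother's strain is not given in the sources used here, and the difference between both lists was not tested. No imprinted locus passed the beta-binomial test. Expression was not measured, so the data do not show which of these genes are expressed from 1 allele in these ES cells.

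Olfactory receptor genes were shifted towards 129, with 214 of 455 loci higher on 129, 98 on Cas and 143 not passing. Their median of 0.06 lay above all 10000 random lists, whose central 95% ran from -0.056 to -0.0060. The window of Olfr1447, Olfr1448 and Olfr1449 had 3171 interactions on 129 and 319 on Cas (2.86), while Olfr209 (1943 and 2631; -0.89) and Olfr418 (1235 and 1631; -0.85) were higher on Cas. Vomeronasal receptor genes had 66 of 184 loci higher on 129, 34 on Cas and 84 not passing, with a median of 0.09 at percentile 99.94. Vmn2r11 had 24 interactions on 129 and 1 on Cas, a 129 share of 96.0% (95% interval 79.6 to 99.9%), and Vmn2r68 had 77 and 8. The beta-binomial test called 16 olfactory loci higher on 129 and 0 on Cas, and 4 vomeronasal loci higher on 129 and 5 on Cas. Both families lie in clusters of related genes, and reads of closely similar members may be placed on the wrong one. Averaging neighbouring members first left the olfactory list at percentile 99.6 and the vomeronasal list inside the central 95% for count.

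Strain-variable families, such as the Klra natural killer receptor, cytochrome P450 2 and Ly6 genes, had 34 of 145 loci higher on 129, 50 on Cas and 61 not passing. Their median of -0.08 lay at percentile 2.39 and their mean was -0.038. Klra3 (17 interactions on 129 and 3 on Cas, a 129 share of 85.0% with an interval of 62.1 to 96.8%) and Ly6c1 (105 and 29) were higher on 129, and Cyp2c40 (10 and 20) on Cas. Klra9 (11 and 19) did not pass. No locus of these families passed the beta-binomial test, where Klra3, Ly6c1 and Cyp2c40 had Benjamini-Hochberg adjusted p of 0.696, 0.079 and 0.690. Numbered zinc finger genes had 84 of 287 loci higher on 129, 105 on Cas and 98 not passing, with a median of -0.052 at percentile 9.95. Zfp277 (3514 and 594; 2.11) and Zfp949 (3091 and 831; 1.44) were higher on 129, and Zfp993 (16 and 44; -1.86) and Zfp981 (16 and 43; -1.83) on Cas, all 4 also by the beta-binomial test. Zfp993 and Zfp981, both on chromosome 4, also had the same log2 distance ratio of 1.72. They may rest on a shared window and need not be separate calls.

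Ribosomal protein genes had 23 of 73 loci higher on 129, 29 on Cas and 21 not passing (median -0.061, percentile 19.3). Rpl37a (3600 and 1424; 0.88) and Rps12 (1934 and 820; 0.78) were at the 129 end, and Rps6 (2047 and 2471; -0.72) and Rps3a1 (2649 and 3122; -0.69) at the Cas end. Rps12 lies on chromosome 10, whose median window was itself at 0.24. Histone genes had 6 of 12 loci higher on 129, 3 on Cas and 3 not passing (median 0.05, percentile 90.4), with H2ac6 and its window neighbours at 0.48, H1f7 at 0.17, H1f0 at -0.33 and H1f8 at -0.29. Although the list was named for replication-dependent histone genes, it was picked by symbol pattern, which does not select for that trait. No ribosomal protein or histone locus passed the beta-binomial test. DNA replication genes had 8 of 26 loci higher on 129, 8 on Cas and 10 not passing, with a median of -0.00087 at percentile 78.5 and a mean of 0.10. Mcm4, a subunit of the replicative helicase, had 1885 interactions on 129 and 337 on Cas (2.03) in a window it shares with Prkdc, and was the only locus of the list called by the beta-binomial test (Benjamini-Hochberg adjusted p = 9.56e-07). Mcm10 had 10033 and 4103 (0.84), Gins1 1644 and 1579 (-0.40) and Orc6 6401 and 5565 (-0.25).

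Neuronal adhesion and synapse genes, most of them very long, had 16 of 28 loci higher on 129, 6 on Cas and 6 not passing, with a median of 0.05 at percentile 98.2. The random lists were matched on summed count and not on count per window, which had a median of 755 in this list. Windows with 496 to 980 interactions, a range that holds this value, had a median raw log2 ratio of 0.49, against 0.45 for the median window. Windows without a protein-coding gene had a centred median of 0.04 and those with 1 such gene -0.0066. Whether the list's shift is particular to these genes was therefore not settled. Cntn5 (10710 interactions on 129 and 5660 on Cas; 0.47) and Grm8 (15156 and 8352; 0.41) were higher on 129, and the cadherin genes Cdh12 (1862 and 2093; -0.62) and Cdh9 (1305 and 1451; -0.61) on Cas, none of them by the beta-binomial test. Marker genes of fibroblasts, the cell type of the feeders, had 3 of 24 loci higher on 129, 12 on Cas and 9 not passing, with a median of -0.074 at percentile 22.3. Fn1, the fibronectin gene, had the largest ratio, with 3337 interactions on 129 and 667 on Cas (1.87), and was the only locus of the list called by the beta-binomial test. Col6a1 was at 0.12, Tagln at -0.36 and Sparc at -0.23. Col6a1 lies on chromosome 10, whose median window was at 0.24.

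Of the 15 lists, 5 lay outside the central 95% of random lists for the count ratio: paternally expressed imprinted, olfactory, vomeronasal, strain-variable, and neuronal adhesion genes. For the distance ratio the 5 were the Hox, paternally expressed imprinted, olfactory, vomeronasal and strain-variable lists, all with longer distances on 129. Their median log2 distance ratios were 0.12, 0.13, 0.05, 0.14 and 0.11, at percentiles 97.7, 98.4, 99.98, 99.98 and 99.99. The other 10 lists had distance percentiles from 20.8 for DNA replication genes to 78.9 for zinc finger genes. A percentile describes these libraries and is not a p-value, and random lists do not share the clustering of real gene families. For count, the olfactory list alone stayed outside under all 4 alternatives. With neighbouring members averaged, the paternally expressed imprinted list (percentile 92.9), the vomeronasal list (68.0) and the strain-variable list (8.85) fell inside. Matching on distance as well put the neuronal adhesion list at 95.9 and the strain-variable list at 3.33, and own-chromosome centres put them at 95.2 and 11.5. For distance, averaging neighbours left the vomeronasal list outside and put the Hox, paternally expressed imprinted, olfactory and strain-variable lists at 85.5, 97.1, 89.7 and 91.2, and matching on distance put the Hox list at 95.9. The binomial test called 67.2% of the 15097 protein-coding loci from which random lists were drawn, and the beta-binomial test 210 of them. Adjusted over the list alone, the counts of calls were those above except that maternally expressed imprinted genes had 7 higher on Cas, vomeronasal genes 65 higher on 129 and strain-variable families 49 higher on Cas.

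**Figure D5:**
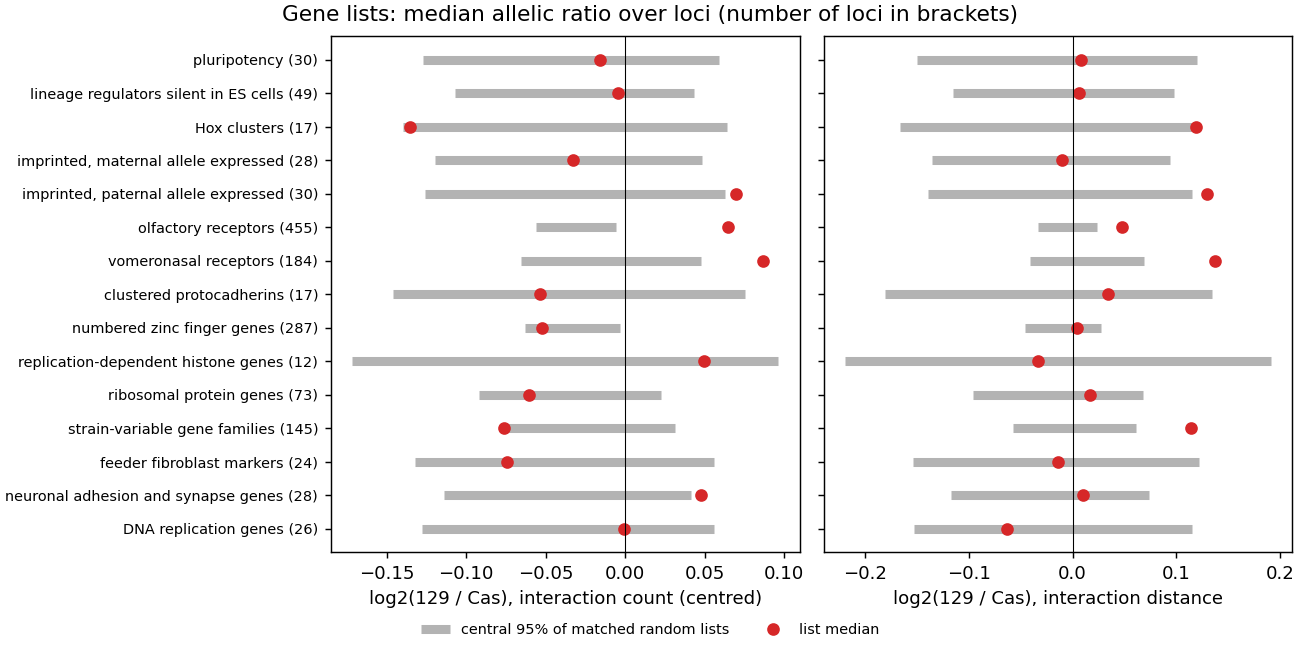
Median log2 ratio of 129 to Cas over the loci of each gene list, for interaction counts (left, centred on the autosomal median) and interaction distances (right), as red points, with grey bars for the central 95% of 10000 matched random lists. The olfactory and vomeronasal lists lie to the right of their bars in both panels, at 0.06 and 0.09 for counts.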

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

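Counts divided by 2, the added 2-fold limit, the omission of chromosomes 8, 10 and 14 and the centring of neighbours per chromosome were chosen only after the results were seen. The 129 share was 57.81% as the median over windows and stayed at 57.6% without the 1% of windows with the largest counts or without those 3 chromosomes. The number of windows called was 36272 against an equal share of both alleles, 14461 with counts divided by 2, 1413 when a 2-fold ratio was also required and 413 with the beta-binomial test, of which all 413 were among the 22494. It was 22450 to 22512 with other count minimums, 21987 against each chromosome's own share, 17862 at a threshold of 0.01 and 18514 of 36849 windows without the 3 chromosomes. Regions called numbered 3502 at 500 kb, 1058 at 2 Mb and 10 with the beta-binomial test, where the number of regions tested also changed with their size (4620 and 1209). The median distance ratio was 0 under each of its 4 alternatives, and r between count and distance ratios ran from -0.108 to -0.096. Without adjacent windows, the correlation of distance ratios at 50 to 200 kb was 0.119 and that of count ratios 0.194. With random lists matched on distance as well, 3 lists lay outside the central 95% for count, and with neighbouring members averaged 2 for count and 1 for distance, where fewer values enter each median; the cause of the other changes was not tested. Among the gene list medians under the alternatives, 103 stayed within their interval and 2 moved out of it, the vomeronasal distance ratio to 0.34 with neighbours averaged and the protocadherin count ratio to 0.03 with chromosome centring. Matching on distance as well changes only the random lists, so the medians counted under that alternative could not move. The 24 windows named first for count kept their direction and their call under every alternative that tested them, and the high-count windows named after their values were seen were not run under the alternatives. Of the 6 regions of 1 Mb named by p, 5 lost their call with the beta-binomial test. The pseudocount could change no call, since the binomial test uses the raw counts. Restricting to autosomes could remove no window, since all windows are autosomal, and the alternatives for the X chromosome were not run. No paired analysis was possible because both replicates are pooled in 1 value per allele. The standard deviation of log2 ratios was 0.64 in windows below the lower count quartile and 0.36 in those above the upper, so single ratios at low counts are the least certain.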

Other observations

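The distance levels of gene lists, the set of isolated windows and the test of whether a few windows carry the shift of chromosome 10 were chosen only after the results were seen, and the bound of the feeder test was altered then, as stated with its value.

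The interaction distance of gene lists was also taken over both alleles, in all windows that a gene's body overlaps and not at promoters alone. It was set against random lists matched on count per window, as a first matching, and against lists matched on summed count, as a second. Neuronal adhesion and synapse genes had a median interaction distance of 3040 kb, against a central 95% of 358 to 930 kb by the first matching (percentile 100 by both), but these genes span a median of 21 windows each. Windows without a protein-coding gene had median distances of 912 kb on 129 and 906 kb on Cas, so the value need not be that of the promoters. Clustered protocadherins had 210.5 kb (74.9 to 171.5 kb; percentiles 99.8 and 99.2), but their 17 loci form 1 cluster. Paternally expressed imprinted genes had 231 kb (117 to 225 kb; 98.2 and 99.5). DNA replication genes had 72.7 kb (77.5 to 137 kb; 0.85 and 0.23) and numbered zinc finger genes 110.75 kb (112 to 136 kb; 1.38 and 0.030). The lists' own 95% bootstrap intervals were wide and overlapped those ranges for the last 4 lists, at 110 to 227 kb, 103 to 316 kb, 52.7 to 122 kb and 94 to 129.5 kb, and members were not averaged over neighbours for this measure. Other lists depended on the matching. Olfactory receptor genes, at 155 kb, lay at percentile 100 by the first and 70.6 by the second. Hox genes at 61.3 kb (29.5 and 0.785), histone genes at 65.2 kb (12.7 and 0.81) and ribosomal protein genes at 79.0 kb (5.23 and 0) lay below the central 95% by the second matching alone, and vomeronasal receptor genes (42.2 and 99.6) above it by the second alone.

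The 129 allele held most interactions on all 19 autosomes, 57.57% in total. DNA of the feeder fibroblasts, if it came from a strain read as 129, may add to this share. The median of 24 fibroblast marker loci lay at percentile 22.29 of random lists, which shows no excess at those genes, but 3 loci were higher on 129, Fn1 at 1.87 among them, and a small share of feeder DNA would move all loci alike, so the explanation stays open. The bound first set against it, an upper bootstrap end below 0, was met at -0.030, but it was wrongly set because matched random lists themselves had a median of -0.038. Loss of Cas reads in mapping to the reference, and a true difference between the alleles, were not tested.

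Chromosome 10 had the highest 129 share, 61.1%. A few windows do not carry this shift, since its median window lay at 0.24 and all 13 bins of 10 Mb were above 0. More copies of the 129 chromosome, or fewer of the Cas chromosome, in part of the cells could produce an even shift, and the standard deviation of its bin medians, 0.077, was inside the range of the other chromosomes (0.056 to 0.146). Levels per allele did not settle which copy would have changed, because with windows matched on gene content the chromosome lay at -0.0039 on 129 and -0.24 on Cas, both within the range of the other 18. Copy number and an allelic difference in contacts along the whole chromosome thus cannot be told apart here.

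In 95 windows with 1000 or more interactions the alleles differed by 4-fold or more, 86 of them higher on 129. A regional difference alone would shift the adjacent windows as well, whose median ratio in the same direction was 0.33 (95% bootstrap interval 0.24 to 0.41), with 79 of 95 on the same side but 2 at 2-fold or more; since an interaction can be counted in both windows, a regional part stays open. On the lower allele these windows lay at 1.16 times the level of gene-free windows within 1 Mb (95% bootstrap interval 1.06 to 1.34; 55 of 77 windows at 0.5 to 2 times and 1 under 0.25), and on the higher allele at 6.24 times. The 4-fold selection by itself holds the lower allele to about 1.56 times that level, so the value cannot tell loss of the captured fragment, which may follow from a strain variant at a HindIII site or under the bait, from other causes of a lower count, but it argues against deletion of the whole window in the set as a group (lower bound 1.06, against 0.25 or less for a deletion). Distances on the lower allele were shorter than in the gene-free windows (median log2 ratio -0.98). Of the 95 windows, 57 held a protein-coding gene, and windows with such genes had shorter distances in general. The distance therefore cannot tell background from remaining contacts. The Slc39a12 window had 44 Cas interactions against a gene-free median of 137.5, below the set's usual level. A biological loss of contacts was not tested.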
